A study of Homo sapiens with 12 samples.

How the data were processed

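Transcript abundance was measured by RNA sequencing in 12 libraries of the human melanoma line WM1366, 4 in each of 3 groups. RNA was extracted with a Qiagen RNeasy mini kit and made into libraries with the TruSeq RNA Library Prep Kit v2, per the labels. Reads were aligned with STAR to GRCh38 and edgeR was used, per the submitters' processing notes, with no versions given in the sources used here. The labels do not say whether the replicates of a group are separate tumours, separate cultures or repeated libraries.

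Each deposited file holds 12931 rows of 1 gene symbol and 1 normalised signal value, which the authors scaled by library size. They carry 12929 distinct symbols, as 2 symbols stand on 2 rows each, and every row was kept and counted as a gene. In every library all values (100%) were whole multiples of 1 step, within 0.001 reads, so that read numbers were recovered by dividing by the step. The unit differed from the read counts assumed beforehand, and limma on log2 values replaced the edgeR test chosen for counts. The edgeR test was kept as an alternative on the recovered reads, where it called 5645 genes for R1 against control, 3564 for R2 against control and 5988 for R2 against R1. Of these, 5525, 3502 and 5881 were also called by limma in the same direction. Every file listed the same genes, and each of them exceeded 1 CPM of the recovered reads, without the authors' scaling, in at least 4 libraries, so no further filter was applied in the main test.

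The recovered reads in the listed genes gave the depth, which leaves out reads in genes that the files do not list. Depth ranged from 20003891 to 39009384 reads per library, and a bound of 3 reads corresponded to values of 0.0728 to 0.158. Confidence intervals (95%) of ratios with few reads were exact binomial (Clopper-Pearson) and, like the 3-read bounds, cover counting error only, since PCR copies are not independent molecules. A gene without a read in a group was given a fold of at least N, from 3 reads over the whole group.

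Values were compared on the log2(value + 0.5) scale with limma 3.58.1 (empirical Bayes with a mean-variance trend) in R 4.3.3. All 12 libraries entered 1 fit with 3 group means. The contrasts were combination R1 minus control, combination R2 minus control, R2 minus R1, and the mean of R1 and R2 minus control. P-values were two-sided and adjusted by the Benjamini-Hochberg method over 12931 genes, and a gene was called, or said to rise or fall, at an adjusted p under 0.05 with no limit on the fold. The added 0.5 makes fold changes of genes with low values smaller than the ratio of their means. Fold values in the text are ratios of group means without it.

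A total of 35 gene lists were fixed by name, of which 32 had at least 3 measured members and were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the 32 lists. They covered the drug pathway (ERK pathway output, RAS-RAF-MEK-ERK components, PI3K-AKT-mTOR-S6 components, receptor tyrosine kinases and ligands, cyclin D-CDK4/6-RB components, E2F and DNA replication genes, G2/M and mitosis genes), melanoma states (melanocyte differentiation, undifferentiated, neural crest-like) and YAP/TEAD targets. Others were extracellular matrix, type I interferon response, MHC class I and class II antigen presentation, NF-kB and inflammatory secretion, p53 targets, the BCL2 family, ATF4 and amino acid synthesis, the unfolded protein response, and cholesterol and fatty acid synthesis. The rest were glycolysis, hypoxia response, the nuclear-coded mitochondrial respiratory chain, cytosolic ribosomal proteins, lysosome and autophagy, NRF2 targets, mitochondrial genome transcripts, and markers of fibroblasts and pericytes, endothelium, leukocytes and macrophages, red blood cells, keratinocytes, and adipocytes and muscle. A list score is the mean log2(value + 0.5) of its members in a library.

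Genes were named by a rule. In each pairwise comparison it took the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 in the higher group and ranges that did not overlap, without uncharacterised loci. It also took up to 2 called members in the direction of each called list with a mean of at least 1, up to 2 called members with the smallest p of each list that was not called, the 6 risen and 6 fallen genes with the largest shared change, and 16 fixed genes. The fixed genes were CDK4, CDK6, CCND1, RB1, CDKN2A, MAP2K1, MAP2K2, NRAS, DUSP6, SPRY4, RPS6, RPS6KB1, PIK3CA, MITF, AXL and MKI67. A few genes that the rule took are not named in the text. Any other gene is said to have been chosen after its values were seen. The groups, contrasts, lists and this rule were fixed before the data were examined.

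Calls in both comparisons with control were set beside the number that independent lists would share, beside 100 simulated draws of unchanged groups against the same controls, and beside fits with different control libraries for each comparison, since both comparisons use the same 4 controls. The alternatives were other scalings (DESeq2 size factors, upper quartile), DESeq2 1.42.0 and edgeR 4.0.16 on recovered reads, an adjusted p under 0.01, a test against a fold of 1.5 (limma treat), and only the groups compared. Further ones were a block on the replicate number, each library left out in turn, another filter on low values, an estimated correlation in camera and the set test fry. Tests were checked on simulated data with changes added to 67, 67 and 66 genes. Of genes changed 1.5-fold, 37.3% were recovered for R1 against control, 20.9% for R2 against control and 23.9% for R2 against R1. At 2-fold these shares were 79.1%, 65.7% and 68.7%, and at 4-fold 98.5%, 97.0% and 90.9%. Unchanged genes called numbered 2, 4 and 7 of those simulated. With so few changed genes the Benjamini-Hochberg limit is stricter than with the many genes called here. These shares and counts therefore do not estimate the recovery or false calls of the real tests.

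The files give gene symbols alone. Positions came from GENCODE version 29 on GRCh38, which placed 11802 (91.3%) of the 12931 genes. Neighbouring genes were searched for stretches of shared change in windows of 25 genes, against 1000 permutations of gene order. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for positions and plots. Sequence variants were not analysed here.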

Results

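Gene expression was measured by RNA sequencing in WM1366, an established human cutaneous melanoma line known to carry an activating NRAS mutation. The 12 libraries formed 3 groups of 4. The diet named in the labels was a control diet for the control group and a diet with MEK and CDK4/6 inhibitors for the groups named R1 and R2. The series describes xenograft tumours that progressed, and concerns resistance acquired under such combinations. The sample labels describe melanoma cells in culture medium, and their treatment text names the MEK inhibitor PD0325901 and the CDK4/6 inhibitor palbociclib for every sample, control included. They do not say what separates R1 from R2. Recovered reads in the listed genes numbered 39009384, 21456002, 27286885 and 31353293 in R1 replicates 1 to 4. They numbered 34762198, 21789510, 30886061 and 21978459 in R2, and 24525658, 25229531, 20844670 and 20003891 in control. Values are normalised read counts, as mean ± SD with n = 4 per group. In brackets, a signed number before an adjusted p is a log2 fold change, and a gene rose or fell where its adjusted p was under 0.05. A count given as alone was adjusted over the list alone, and pairs of counts are in the order up, then down. P-values measure the spread between these samples alone, since the labels do not say whether replicates are separate tumours or cultures.

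The groups separated along the first principal components of all listed genes. The first, with 44.3% of the variance, set R1 apart from R2 and control, the next (30.1%) set R2 apart from control, and the next (8.65%) set R1 replicate 2 apart from the other R1 libraries. On this last component control replicates 3 and 4 (-13.5 and -10.9) and R2 replicate 2 (-13.0) lay on the side of R1 replicate 2 (-38.6). Control replicates 1 and 2 lay on the other side (18.6 and 10.8). Mitochondrial genome transcripts took 2.39% ± 0.515 (SD, n = 4) of reads in R1, 7.45% ± 2.43 in R2 and 8.17% ± 1.99 in control. R2 replicate 3 was at 3.86%, against 8.11% to 9.19% in the other R2 libraries. Cytosolic ribosomal protein mRNAs took 10.3% ± 1.03 of reads in R1, 6.09% ± 0.506 in R2 and 5.76% ± 0.334 in control.

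**Figure D1:**
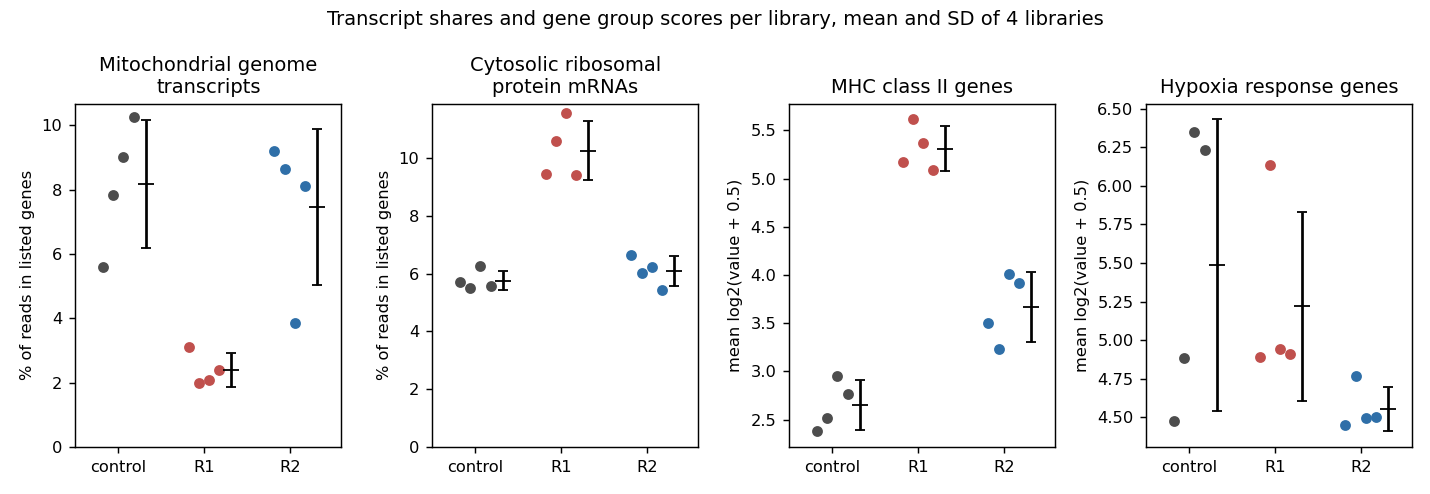
Percent of reads in listed genes from mitochondrial genome transcripts and from cytosolic ribosomal protein mRNAs, and mean log2(value + 0.5) of MHC class II and hypoxia response genes, on the y axes for control, R1 and R2; each point is 1 library, and the bar beside it is the mean ± SD of 4. The 4 R1 libraries have 1.99% to 3.12% mitochondrial transcripts, below every R2 and control library, and the hypoxia score of control spans 4.47 to 6.35.

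The first comparison asked which transcripts differed between the R1 group, on the inhibitor diet, and control. NRAS, the RAS GTPase that feeds the RAF-MEK-ERK cascade, was 7.77-fold higher in R1, at 978 ± 109 against 126 ± 12.6 in control (log2 fold change 2.95, SE 0.13, adjusted p = 6.2e-10). Ribosomal protein mRNAs and the MHC class II genes, which present peptides to helper T cells, were broadly higher, with 65 of 77 and 10 of 12 members risen. Transcripts of the mitochondrial genome, which codes for subunits of the respiratory chain, were lower, with 12 of 13 fallen. MYH10, the heavy chain of non-muscle myosin IIB, went from 72.0 ± 4.10 in control to 0.0413 ± 0.0572, with 6 reads in all 4 R1 libraries together (log2 fold change -7.07, SE 0.14, adjusted p = 3.0e-13). In all, 2900 genes rose and 2767 fell of 12931, and 699 and 662 of these changed more than 2-fold.

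The largest rises under the rule were in G0S2, an inhibitor of the fat-splitting lipase ATGL (63.5 ± 14.1 against 0.137 ± 0.0931, log2 fold change 6.64, SE 0.18, adjusted p = 4.8e-12), and LAMA4, a laminin chain (79.8 ± 33.2 against 0.564 ± 0.198, log2 fold change 6.18, adjusted p = 7.4e-10). HSD11B1, which makes cortisol from cortisone (42.3 ± 23.4 against 0.0490 ± 0.0434, log2 fold change 6.12, adjusted p = 3.2e-09), and TNFAIP8L2, a regulator of immune signalling (32.6 ± 4.0 against 0.0426 ± 0.0325, 5.92, adjusted p = 2.4e-12), came next. The largest falls beside MYH10 were in SDPR, a coat protein of caveolae (0.0763 ± 0.0347 against 50.8 ± 2.24, -6.48, adjusted p = 5.5e-12), and GDA, guanine deaminase, with 3 reads in R1 (ratio of the higher to the lower group 1564, 95% counting interval 535 to 7586). HBE1, the embryonic epsilon globin (-5.58, adjusted p = 1.2e-10), and the transcription factor SOX15 (-5.32, adjusted p = 1.2e-10) followed. Each of these genes had all 4 R1 libraries on 1 side of all 4 control libraries, as had every gene named under the rule and called here except CDKN2A and RB1. NRAS lies on chromosome 1, 114704469 to 114716894 (GRCh38), G0S2 on chromosome 1, 209675420 to 209676388, LAMA4 on chromosome 6, 112108760 to 112254939 and MYH10 on chromosome 17, 8474205 to 8630761. HSD11B1 lies close to G0S2, at 209686178 to 209734950 of chromosome 1, so these rises may not be separate. MYH10 and SOX15 lie in a stretch of chromosome 17, found after the values were seen, in which 137 of 193 genes fell, and HBE1 lies in one of chromosome 11 in which 98 of 146 fell.

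Among the drug targets, CDK4 rose (439 ± 77.1 against 286 ± 25.3, log2 fold change 0.61, SE 0.13, adjusted p = 0.0017), as did MAP2K1, which codes for MEK1 (99.9 ± 14.8 against 69.4 ± 7.25, log2 fold change 0.52, adjusted p = 0.0019). CDK6 (0.01, adjusted p = 0.955) and MAP2K2 (0.10, adjusted p = 0.562), which codes for MEK2, did not pass the test. CCND1, cyclin D1, rose to 545 ± 111 from 268 ± 57.8 (1.02, adjusted p = 0.0004). DUSP6 and SPRY4, feedback inhibitors that ERK activity induces, rose as well, by 0.66 and 1.30 on the log2 scale (adjusted p = 0.0058 and 4.0e-05). RPS6, the ribosomal protein read as a marker of mTOR signalling when phosphorylated, rose (0.74, adjusted p = 0.00035), while RPS6KB1 (-0.34, adjusted p = 0.0648) and PIK3CA (0.32, adjusted p = 0.0539) did not pass. AXL, a receptor tyrosine kinase of undifferentiated melanoma (825 ± 144 against 1584 ± 80.1, -0.95, adjusted p = 4.4e-05), MITF, the transcription factor of the melanocyte lineage (-1.11, adjusted p = 0.00022), and CDKN2A, which codes for the CDK4/6 inhibitor p16 (-0.49, adjusted p = 0.0081), fell. The proliferation marker MKI67 did not pass (-0.31, adjusted p = 0.187). RB1 fell (-0.35, adjusted p = 0.0431), a call lost without R1 replicate 2 or 3, R2 replicate 1 or 4 or control replicate 1, 2 or 4 (adjusted p up to 0.124). RPS6KB1 was called without R1 replicate 4 or control replicate 3 (lowest adjusted p = 0.0135), and PIK3CA without R1 replicate 3 (adjusted p = 0.0028).

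**Figure D2:**
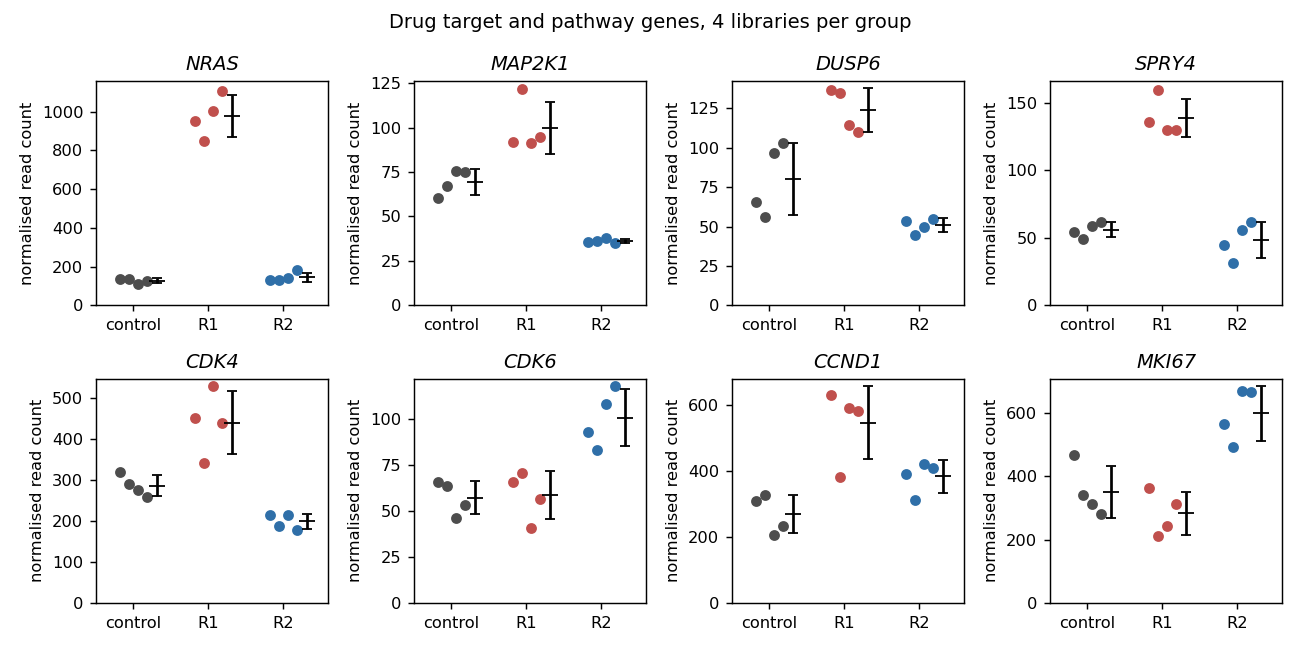
Normalised read counts (y axes, from 0) of 8 drug target and pathway genes in control, R1 and R2; points are single libraries, and the bar beside them is the mean ± SD of 4. NRAS has a mean of 978 in R1 against 144 in R2 and 126 in control, while MAP2K1, DUSP6 and CDK4 are highest in R1 and lowest in R2.

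The 14 tested genes within 1 Mb of NRAS, looked up after its value was seen, did not share its rise. Of these, 3 rose and 4 fell in R1, with a median log2 fold change of 0.16.

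**Figure D3:**
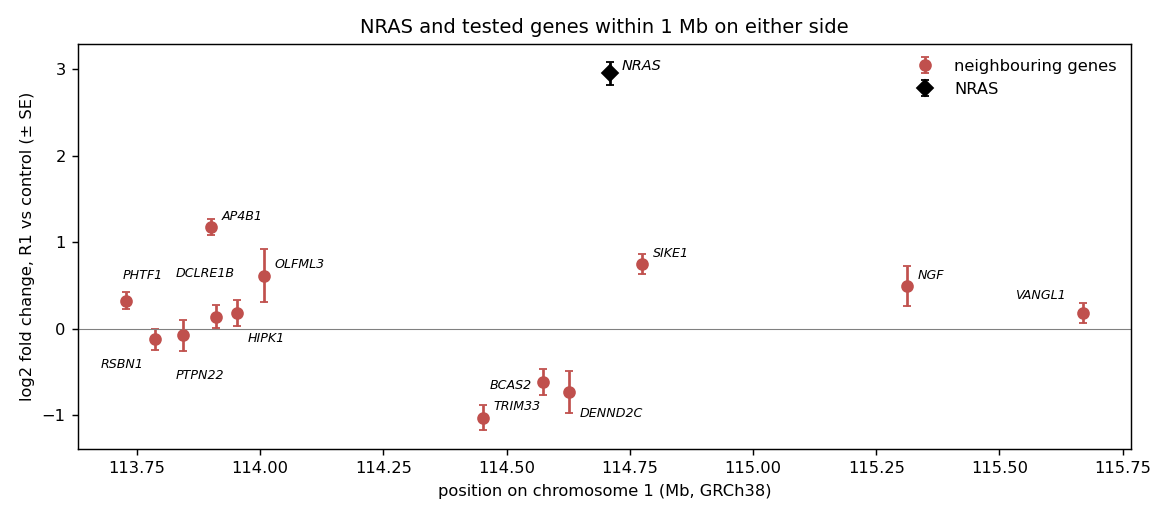
Log2 fold change of R1 against control (y axis, points, with bars of ± SE) of NRAS (diamond) and 13 of its 14 tested neighbours (circles) by position on chromosome 1 in Mb of GRCh38 (x axis). NRAS is at 2.95, while the plotted neighbours lie between -1.03 (TRIM33) and 1.17 (AP4B1), genes taken by position after the value of NRAS was seen.

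Of the MHC class II genes 10 rose and 0 fell of 12 measured (11 and 1 adjusted over the list alone), with a median log2 fold change of 2.64, or 2.82 with HLA-DRB5 and HLA-DQB1, chosen after their values were seen, which had 3 control reads each, at the bound of those reads. By camera the class II list had adjusted p = 2.1e-07, and adjusted p = 0.534 with an estimated correlation. HLA-DRB1 reached 167 ± 35.8 against 2.51 ± 1.14 (log2 fold change 5.84, SE 0.25, adjusted p = 5.2e-10) and HLA-DRA 111 ± 19.2 against 3.90 ± 1.12 (4.68, adjusted p = 7.2e-10), where reads of HLA-DRB1 and its paralog HLA-DRB5 cannot be assigned with certainty. The member that fell over the list alone was RFX5, a class II transcription factor chosen after its values were seen (-0.24, adjusted p = 0.0555). Leukocyte and macrophage markers, of which 3 of 20 were measured, had a summed value of 23.7 ± 5.43 in R1 against 8.55 ± 1.17 in control and a median log2 fold change of 1.40 (2 risen, list not called). Of the cytosolic ribosomal protein genes 65 rose and 1 fell of 77 measured (65 and 1 adjusted over the list alone), with a median of 0.81, led by RPS21 (2.01, adjusted p = 7.3e-08) and RPL31 (1.99, adjusted p = 3.6e-08). By camera the ribosomal protein list had adjusted p = 2.4e-18, and adjusted p = 0.691 with an estimated correlation. RPS26, chosen after its values were seen, fell with overlapping ranges (-0.77, adjusted p = 0.0093). Of the nuclear-coded respiratory chain genes 29 rose and 2 fell of 51 measured (30 and 3 adjusted over the list alone), median 0.41, among them COX7C (1.34, adjusted p = 1.4e-06) and UQCRQ (1.25, adjusted p = 2.0e-06). By camera the respiratory chain list had adjusted p = 0.00011, and adjusted p = 0.912 with an estimated correlation. UQCRB (-0.38, adjusted p = 0.0137) and UQCR10 (-0.64, adjusted p = 0.0013, overlapping ranges), also chosen after their values were seen, fell.

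Among mitochondrial genome transcripts 0 rose and 12 fell of 13 measured (0 and 12 adjusted over the list alone), median -1.81. By camera the mitochondrial genome list had adjusted p = 1.5e-06, and adjusted p = 0.691 with an estimated correlation. MT-ND4 went from 18163 ± 5640.0 to 3487 ± 674 (log2 fold change -2.34, SE 0.30, adjusted p = 2.6e-05) and MT-ND3 from 2049.7 ± 651 to 411 ± 108 (-2.29, adjusted p = 1.5e-05). MT-ND6, chosen after its values were seen, did not pass (-0.20, adjusted p = 0.408). Of the endothelial markers 4 rose and 0 fell of 6 measured (5 and 0 adjusted over the list alone), median 1.00. By camera the endothelial list had adjusted p = 0.0094, and adjusted p = 0.691 with an estimated correlation. TIE1, an endothelial receptor kinase, was at 394 ± 54.6 against 139 ± 14.6 (1.5, adjusted p = 3.0e-07), and EGFL7, a secreted vessel factor, at 16.2 ± 3.32 against 3.61 ± 1.04 (2.03, adjusted p = 1.3e-06). The summed endothelial marker value was 554 ± 71.9 in R1, 205 ± 31.9 in R2 and 228 ± 21.2 in control. Reads of mouse host cells, possible in xenograft tumours, were not separated here. Values of endothelial, leukocyte and fibroblast markers may include them and cannot be assigned to the melanoma cells alone. The lower mitochondrial share of R1 went along with each of these gene groups.

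The other cell cycle and pathway lists were not called. The E2F and DNA replication genes had 2 risen and 14 fallen of 51 members (2 and 10 adjusted over the list alone, adjusted p = 0.0884), with CHAF1B (-1.27, adjusted p = 0.0003) and SLBP (-0.76, adjusted p = 0.00056) lower, and the list was called down without R1 replicate 1, 3 or 4 or control replicate 3 or 4 (adjusted p of 0.00891 to 0.0305). The G2/M and mitosis genes had 0 risen and 7 fallen of 40 members (0 and 5 adjusted over the list alone, adjusted p = 0.149), with FOXM1 (-1.33, adjusted p = 0.00026) and PLK1 (-1.13, adjusted p = 0.0012) lower, called down without R1 replicate 4 (adjusted p = 0.0233). Both list shifts rested on R1 replicate 2, whose scores of both lists were the lowest of R1. Without it the adjusted p was 0.761 for E2F (down) and 0.751 for G2/M, whose direction turned up. ERK pathway output had 5 risen and 7 fallen of 26 members (5 and 7 adjusted over the list alone, adjusted p = 0.747), with TFAP2C (-5.28, adjusted p = 9.6e-09) and EPHA4 (1.61, adjusted p = 9.0e-07). RAS-RAF-MEK-ERK components had 8 risen and 3 fallen of 23 members (9 and 3 adjusted over the list alone, adjusted p = 0.247). Cyclin D-CDK4/6-RB components had 7 risen and 4 fallen of 21 members (7 and 5 adjusted over the list alone, adjusted p = 0.747), with CDKN2D (1.34, adjusted p = 6.9e-05). PI3K-AKT-mTOR-S6 components had 8 risen and 8 fallen of 35 members (9 and 8 adjusted over the list alone, adjusted p = 0.747), with AKT1S1 (-1.19, adjusted p = 7.2e-07). Receptor tyrosine kinases and ligands had 4 risen and 15 fallen of 31 members (4 and 15 adjusted over the list alone, adjusted p = 0.0827), with MERTK (-2.19, adjusted p = 3.2e-07).

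Melanocyte differentiation had 4 risen and 5 fallen of 15 members (4 and 5 adjusted over the list alone, adjusted p = 0.747), with PMEL, a melanosome protein (2.24, adjusted p = 1.5e-06) and BCL2A1 (2.65, adjusted p = 9.5e-06). The undifferentiated list had 8 risen and 12 fallen of 31 members (8 and 14 adjusted over the list alone, adjusted p = 0.159), with F3, tissue factor (-2.37, adjusted p = 2.4e-07). The neural crest-like list had 5 risen and 5 fallen of 13 members (6 and 5 adjusted over the list alone, adjusted p = 0.747), with GFRA1 (-4.60, adjusted p = 2.9e-09) and ITGA6 (1.36, adjusted p = 2.5e-06). YAP/TEAD targets had 1 risen and 7 fallen of 23 members (1 and 7 adjusted over the list alone, adjusted p = 0.129), with CRIM1 (-1.38, adjusted p = 2.5e-07). Extracellular matrix had 13 risen and 8 fallen of 35 members (14 and 10 adjusted over the list alone, adjusted p = 0.747), with LAMA4 above and TIMP3, an inhibitor of matrix proteases, without a read in R1 and at least 64.4-fold lower. Interferon response genes had 13 risen and 7 fallen of 42 members (14 and 7 adjusted over the list alone, adjusted p = 0.747), with IRF7 (-3.15, adjusted p = 3.9e-08) and ISG15 (1.17, adjusted p = 6.3e-05). MHC class I had 9 risen and 2 fallen of 19 members (9 and 2 adjusted over the list alone, adjusted p = 0.119), with TAP1 (1.92, adjusted p = 1.8e-07), called up without control replicate 3 (adjusted p = 0.0456). NF-kB and inflammatory secretion had 6 risen and 3 fallen of 26 members (6 and 2 adjusted over the list alone, adjusted p = 0.747), with IL6 (-3.63, adjusted p = 7.1e-06) and MMP1 (3.0, adjusted p = 0.0023).

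Targets of p53 had 10 risen and 1 fallen of 26 members (10 and 1 adjusted over the list alone, adjusted p = 0.0884), with the death receptor gene TNFRSF10B (1.19, adjusted p = 3.9e-06). The BCL2 family had 7 risen and 2 fallen of 17 members (7 and 2 adjusted over the list alone, adjusted p = 0.247), with BIK, a killer protein, up from 3 control reads (ratio of the higher to the lower group 92.0, 95% counting interval 31.2 to 448) and BMF (-2.46, adjusted p = 8.8e-06). Counts for ATF4 and amino acid synthesis were 7 and 9 of 36 (7 and 9 alone, adjusted p = 0.747), up and down in that order. The unfolded protein response had 4 and 2 of 23 (4 and 2 alone, adjusted p = 0.749). Cholesterol synthesis had 1 and 3 of 24 (1 and 1 alone, adjusted p = 0.747). Fatty acid synthesis had 2 and 6 of 19 (2 and 6 alone, adjusted p = 0.747). Glycolysis had 1 and 6 of 22 (1 and 6 alone, adjusted p = 0.327). Hypoxia response had 3 and 1 of 27 (3 and 1 alone, adjusted p = 0.747), with ADM, adrenomedullin (-4.08, adjusted p = 3.7e-06). Lysosome and autophagy had 10 and 5 of 34 (10 and 5 alone, adjusted p = 0.747), with CTSL (1.66, adjusted p = 3.0e-06). NRF2 targets had 8 and 4 of 20 (8 and 4 alone, adjusted p = 0.398). Fibroblast and pericyte markers had 2 and 1 of 8 (2 and 1 alone, adjusted p = 0.747). Leukocyte and macrophage markers had 2 and 0 of 3 (2 and 0 alone, adjusted p = 0.115). For extracellular matrix the median was -0.18 and the mean 0.42 with the test upward, and for neural crest they were 0.13 and -0.18 with the test upward. For the unfolded protein response (-0.01, 0.02) and lysosome (-0.02, 0.07) the median was below 0 as well, with the mean and test above it.

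The next comparison asked the same of R2 against control. NRAS did not pass the test here (144 ± 24.8 against 126 ± 12.6, log2 fold change 0.19, SE 0.13, adjusted p = 0.304). MAP2K1 fell to 36.2 ± 1.03 from 69.4 ± 7.25 (log2 fold change -0.93, SE 0.11, adjusted p = 2.9e-05), and 13 of 26 genes that report ERK activity fell while 2 rose. CDK6, the other kinase that palbociclib inhibits, rose to 100.4 ± 15.4 from 57.2 ± 9.17 (log2 fold change 0.81, adjusted p = 0.0028) and CDK4 fell (-0.52, adjusted p = 0.0077). MHC class II genes rose here too, 7 of 12, with HLA-DRB1 at 26.4 ± 8.10 against 2.51 ± 1.14 (3.18, adjusted p = 4.7e-07), and MKI67 rose to 598 ± 85.9 from 349 ± 81.5 (0.79, adjusted p = 0.0052). In all, 1756 genes rose and 1911 fell of 12931, 343 and 598 of them by more than 2-fold.

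The largest rises under the rule were in C1orf94, from 2 control reads (ratio of the higher to the lower group 1068, 95% counting interval 295 to 8827), and COL24A1, a fibrillar collagen (21.3 ± 6.34 against 0.0787 ± 0.0211, log2 fold change 5.20, SE 0.20, adjusted p = 2.8e-10). HCLS1, a cortactin relative of blood cells (21.8 ± 9.99 against 0.226 ± 0.0521, 4.84, adjusted p = 1.1e-07), EMC10, of a membrane protein insertion complex (53.8 ± 16.4 against 1.55 ± 0.267, 4.69, adjusted p = 3.9e-10), and GPR65, a proton-sensing receptor (4.66, adjusted p = 9.4e-10), followed. Beside MYH10 (0.0385 ± 0.0592 against 72.0 ± 4.10, -7.08, adjusted p = 3.0e-13), the largest falls were in GDA (-6.17, adjusted p = 1.9e-12), SOX15 (-5.39, adjusted p = 2.1e-10), SNHG14, a non-coding RNA with 3 reads in R2 (ratio of the higher to the lower group 1127, 95% counting interval 385 to 5469), and FAM83H with 1 read (ratio of the higher to the lower group 2007, 95% counting interval 359.8 to 79337). Named genes called here had all 4 R2 libraries on 1 side of all 4 control libraries except CCND1, DDIT4, PECAM1 and SLC2A3. C1orf94 lies on chromosome 1, 34166883 to 34219131, next to CSMD2, and SNHG14 on chromosome 15, 24978583 to 25419462. SNHG14 and MAP2K1 lie in a stretch of chromosome 15 in which 289 of 371 genes fell, found after the values were seen.

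Of ERK pathway output genes 2 rose and 13 fell of 26 measured (2 and 14 adjusted over the list alone), median -0.54. By camera ERK pathway output had adjusted p = 0.0052, and adjusted p = 0.946 with an estimated correlation. DUSP4, a phosphatase that ERK induces, was at 7.10 ± 6.21 against 39.3 ± 7.20 (-2.87, adjusted p = 0.00077), PHLDA1 at 102 ± 9.27 against 534 ± 151 (-2.35, adjusted p = 9.8e-07) and DUSP6 at 50.8 ± 4.52 against 80.3 ± 22.9 (-0.61, adjusted p = 0.0144). SPRY4 did not pass (-0.25, adjusted p = 0.307). The members that rose were EPHA4 (1.40, adjusted p = 5.8e-06), an ephrin receptor chosen here after its values were seen, and CCND1 (0.53, adjusted p = 0.0400). The DUSP6 call was lost without control replicate 3 or 4 (adjusted p up to 0.0529), and that of CCND1 without R2 replicate 1, 3 or 4 or control replicate 3 or 4 (adjusted p up to 0.128). Of receptor tyrosine kinases and ligands 2 rose and 12 fell of 31 measured (3 and 13 adjusted over the list alone), median -0.27. By camera the receptor kinase list had adjusted p = 0.0046, and adjusted p = 0.946 with an estimated correlation. PDGFRB (0.331 ± 0.167 against 4.03 ± 2.02, -2.34, adjusted p = 0.0003) and MERTK (-1.99, adjusted p = 1.3e-06) fell, and AXL did not pass (-0.14, adjusted p = 0.458). RYK (0.27, adjusted p = 0.0355) and FGFR1 (0.71, adjusted p = 0.0216, overlapping ranges), both chosen here after their values were seen, rose.

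Of the MHC class II genes 7 rose and 0 fell of 12 measured (8 and 1 adjusted over the list alone), median 0.87, or 1.19 with members of few control reads at their bound. By camera the class II list had adjusted p = 0.0046, and adjusted p = 0.946 with an estimated correlation. HLA-DRA reached 22.1 ± 5.25 against 3.90 ± 1.12 (2.36, adjusted p = 1.4e-06), and CIITA, the class II transactivator, chosen after its values were seen, fell over the list alone (-0.49, adjusted p = 0.0689). Of ATF4 and amino acid synthesis genes 2 rose and 14 fell of 36 measured (2 and 18 adjusted over the list alone), median -0.42, among them the stress genes DDIT4 (-2.41, adjusted p = 0.0133) and DDIT3 (-2.09, adjusted p = 0.006). By camera the ATF4 list had adjusted p = 0.0046, and adjusted p = 0.946 with an estimated correlation. SLC1A5 (0.51, adjusted p = 0.0104) and PYCR1 (0.85, adjusted p = 0.00014), both chosen after their values were seen, rose. Of the hypoxia response genes 0 rose and 5 fell of 27 measured (0 and 5 adjusted over the list alone), median -0.82, among them ADM (11.7 ± 4.73 against 109 ± 68.2, -3.0, adjusted p = 0.0001) and ANGPTL4 (-2.84, adjusted p = 0.0022). By camera the hypoxia list had adjusted p = 0.0069, and adjusted p = 0.970 with an estimated correlation. Of the glycolysis genes 0 rose and 6 fell of 22 measured (0 and 6 adjusted over the list alone), median -0.31, among them ENO2 (-1.82, adjusted p = 0.0047) and the glucose transporter gene SLC2A3 (-1.80, adjusted p = 0.0286). By camera the glycolysis list had adjusted p = 0.0348, and adjusted p = 0.970 with an estimated correlation. ENO2 and SLC2A3 lie in a stretch of chromosome 12 in which 42 of 71 genes fell, found after the values were seen.

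Control replicates 1 and 2 lay apart from 3 and 4, and not in these last groups alone. Over all genes with at least 10 reads in a pair of libraries, the chi-square per degree of freedom between control libraries was 16.1 for replicates 1 and 2 and 11.3 for 3 and 4. It was 44.3 to 77.4 for the other pairs. R2 replicates 1 and 2 lay apart from 3 and 4 on principal component 4 (-15.8 and -30.3 against 20.7 and 23.8). Their NF-kB scores were 3.75 and 3.95 against 5.20 and 5.23. By chi-square the R2 pairs were less distinct, at 37.4 for replicates 1 and 2, 50.4 for 3 and 4 and 49.4 to 114 for the others. Where the libraries of a pair share a source, n = 4 overstates the replication. Control scores for ERK pathway output were 6.32, 6.30, 6.68 and 6.66 in replicates 1 to 4, and for ATF4 and amino acid synthesis 5.59, 5.63, 5.91 and 5.81. Both lists stayed called without any 1 control library (adjusted p up to 0.0115). Leaving out 1 library keeps its partner, so these fits do not test the split of the controls into pairs, and the same holds for R2. R2 scores for ERK pathway output were 5.64, 5.55, 6.06 and 6.18 in replicates 1 to 4. All lay below the control scores, with R2 replicates 3 and 4 the closest to them. The hypoxia scores of control were 4.47, 4.88, 6.35 and 6.23, against 4.45 to 4.77 in R2, and its glycolysis scores were 8.10, 8.19, 9.09 and 8.90. Without control replicate 3 or 4 the hypoxia list was not called (adjusted p = 0.0828 and 0.0986), nor was glycolysis (0.247 and 0.145), which was also lost without R2 replicate 1 (0.0503) or 4 (0.0588). SLC2A3 was lost without R2 replicate 1, 3 or 4 or control replicate 3 or 4 (adjusted p up to 0.0929). Of the endothelial markers 0 rose and 2 fell of 6 measured (0 and 4 adjusted over the list alone), median -0.64, lost without R1 replicate 3 (adjusted p = 0.0532), R2 replicate 2 (0.133) or control replicate 3 (0.0828) or 4 (0.0585). By camera the endothelial list had adjusted p = 0.0411, and adjusted p = 0.946 with an estimated correlation. EGFL7 had 1 read in R2 (ratio of the higher to the lower group 385, 95% counting interval 68.6 to 15262), and PECAM1 (-1.09, adjusted p = 0.0332) was lost without R2 replicate 3 or 4 or control replicate 2, 3 or 4 (adjusted p up to 0.110).

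The remaining lists were not called. E2F and DNA replication genes had 3 risen and 2 fallen of 51 members (2 and 2 adjusted over the list alone, adjusted p = 0.651), with E2F8, an E2F family repressor (3.5, adjusted p = 9.3e-07) and CCNE1, cyclin E1 (1.13, adjusted p = 2.3e-05). G2/M and mitosis genes had 3 risen and 5 fallen of 40 members (3 and 4 adjusted over the list alone, adjusted p = 0.643), with HMMR (1.37, adjusted p = 0.0033) and PRC1 (-0.92, adjusted p = 0.0016). Cyclin D-CDK4/6-RB components had 5 risen and 3 fallen of 21 members (5 and 5 adjusted over the list alone, adjusted p = 0.865), with CDKN2C (0.91, adjusted p = 0.0013). RB1 (-0.26, adjusted p = 0.156) and CDKN2A (-0.36, adjusted p = 0.0551) did not pass, although CDKN2A did without R1 replicate 3, R2 replicate 2 or control replicate 2 (lowest adjusted p = 0.0311). RAS-RAF-MEK-ERK components had 5 risen and 2 fallen of 23 members (6 and 2 adjusted over the list alone, adjusted p = 0.239), with NF1, a RAS inactivator (0.86, adjusted p = 0.00045) and MAP2K2 (0.14, adjusted p = 0.426). PI3K-AKT-mTOR-S6 components had 8 risen and 3 fallen of 35 members (8 and 5 adjusted over the list alone, adjusted p = 0.609), with AKT2 (-0.85, adjusted p = 1.5e-05), RPS6 (0.19, adjusted p = 0.283), RPS6KB1 (0.20, adjusted p = 0.328) and PIK3CA (0.24, adjusted p = 0.170). Melanocyte differentiation had 3 risen and 6 fallen of 15 members (3 and 6 adjusted over the list alone, adjusted p = 0.241), with MITF (-0.70, adjusted p = 0.0093) and RAB27A (-1.15, adjusted p = 5.5e-06). The undifferentiated list had 3 risen and 7 fallen of 31 members (4 and 8 adjusted over the list alone, adjusted p = 0.188), with F3 (-2.74, adjusted p = 7.3e-08). The neural crest-like list had 3 risen and 5 fallen of 13 members (3 and 5 adjusted over the list alone, adjusted p = 0.831), with L1CAM (-3.43, adjusted p = 6.2e-05). YAP/TEAD targets had 3 risen and 5 fallen of 23 members (3 and 5 adjusted over the list alone, adjusted p = 0.651), with CTGF (-2.10, adjusted p = 0.00015).

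Extracellular matrix had 6 and 5 of 35 (6 and 5 alone, adjusted p = 0.931), up and down in that order, with LOXL1 (-3.37, adjusted p = 1.9e-08) and TIMP3 at 1 read in R2 (ratio of the higher to the lower group 173, 95% counting interval 30.5 to 6875). Interferon response had 3 and 11 of 42 (3 and 13 alone, adjusted p = 0.513). MHC class I had 3 and 4 of 19 (3 and 4 alone, adjusted p = 0.643), with PDIA3 (-1.48, adjusted p = 0.00018). NF-kB had 1 and 4 of 26 (0 and 4 alone, adjusted p = 0.337), with IL11 (-2.16, adjusted p = 6.8e-05). Of p53 targets there were 5 and 7 of 26 (6 and 9 alone, adjusted p = 0.651). The BCL2 family had 2 and 3 of 17 (2 and 3 alone, adjusted p = 0.513). The unfolded protein response had 0 and 3 of 23 (0 and 2 alone, adjusted p = 0.303), with the chaperone HSPA5 (-1.60, adjusted p = 0.0106). Cholesterol synthesis had 2 and 1 of 24 (2 and 1 alone, adjusted p = 0.513). Fatty acid synthesis had 7 and 5 of 19 (8 and 5 alone, adjusted p = 0.651). Lysosome had 5 and 5 of 34 (5 and 5 alone, adjusted p = 0.901). NRF2 targets had 5 and 2 of 20 (6 and 2 alone, adjusted p = 0.643). The respiratory chain had 6 and 7 of 51 (6 and 7 alone, adjusted p = 0.699). Ribosomal proteins had 4 and 6 of 77 (2 and 5 alone, adjusted p = 0.513). Mitochondrial genome transcripts had 0 and 0 of 13 (0 and 0 alone, adjusted p = 0.651), with 0 unadjusted p under 0.05 in limma and 0 calls by edgeR or DESeq2. Fibroblast markers had 1 and 3 of 8 (1 and 4 alone, adjusted p = 0.303). Leukocyte markers had 1 and 2 of 3 (1 and 2 alone, adjusted p = 0.688), with CSF1R (-1.20, adjusted p = 0.0193), lost without R2 replicate 1 or control replicate 3 or 4 (adjusted p up to 0.0686). Median, mean and test differed in sign for extracellular matrix (0.08, -0.05, down), interferon (0.02, -0.13, down), fatty acid synthesis (-0.09, -0.11, up), lysosome (0.02, -0.01, up) and NRF2 (0.10, -0.02, up).

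A further question was what both groups on the inhibitor diet shared. EMC10 (5.08 in R1 and 4.69 in R2, log2 fold changes against control), GPR65 (3.96 and 4.66), HSD11B1 (6.12 and 3.30), PLEKHA6 (3.48 and 3.22) and HLA-DRB1 (5.84 and 3.18) rose in both. CSMD2 had no control read and was at least 236-fold higher in R1 and at least 296-fold higher in R2. MYH10 (-7.07 and -7.08), GDA (-6.21 and -6.17), SOX15 (-5.32 and -5.39), FAM83H (2 reads in R1, ratio of the higher to the lower group 1123, 95% counting interval 310.3 to 9278), C16orf45 (-4.12 and -4.03) and ADCY6, an adenylyl cyclase (-4.33 and -3.97), fell in both. The adjusted p of these genes ran up to 5.3e-06 in R1 and 2.0e-05 in R2, and SEs from 0.14 to 0.46. A total of 776 genes rose and 837 fell in both groups, and 354 were called in opposite directions. Independent lists of these sizes would share 394, 409 and 804. Simulated unchanged groups against the same controls gave means of 0.04 and 0.34 shared calls up and down. Unchanged groups give few calls of any kind, so these means do not show how many calls independent changes would share. Fits with different control libraries for each comparison gave 286 to 411 genes up and 405 to 514 down in both, and 82 to 333 in opposite directions. The 333 came with control replicates 1 and 2 for R1 and 3 and 4 for R2, where 411 were up and 514 down in both. Separate control libraries do not remove a change of the control itself, where these libraries come from a single tumour or culture.

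Across genes, which are not independent replicates, the fold changes of R1 and R2 had a Pearson r of 0.42 and a Spearman rho of 0.34. Simulated unchanged groups against the same controls gave r = 0.49 ± 0.28 (SD of 100 simulated draws). Those groups hold no changes, so this r is no standard for groups with many changed genes. Both comparisons use the same controls, so r alone does not measure sharing. The covariance was 0.203 against a simulated mean of 0.0210, which also comes from groups without changes. With separate control libraries r was 0.29 to 0.43 and the covariance 0.154 to 0.206, so noise of the same control libraries does not alone give them. A change of the control as a whole stays in these values. The mean of R1 and R2 differed from control in 4553 genes (2291 up, 2262 down). That test took the libraries of each group as replicates, so its count does not measure an effect of the diet. R2 differed from R1 in more genes (6053), and with 1 mean for both groups together the count was 1998.

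The direct comparison of R2 with R1 asked how both groups on the inhibitor diet differed from each other. NRAS was at 144 ± 24.8 in R2 and 978 ± 109 in R1 (log2 fold change -2.77, SE 0.13, adjusted p = 1.2e-09). MAP2K1 (-1.44, adjusted p = 2.8e-07), CDK4 (-1.13, adjusted p = 1.1e-05), DUSP6 (-1.28, adjusted p = 4.0e-05) and SPRY4 (-1.55, adjusted p = 9.0e-06) were lower in R2, while CDK6 (0.79, adjusted p = 0.0018), AXL (0.82, adjusted p = 0.00016), MKI67 (1.10, adjusted p = 0.00026) and RPS6KB1 (0.53, adjusted p = 0.0066) were higher. All 13 mitochondrial genome transcripts were higher in R2 by limma (12 by edgeR and by DESeq2), and 60 of 77 ribosomal protein mRNAs and 11 of 12 MHC class II genes were lower. In all, 2945 genes were higher and 3108 lower in R2 of 12931, with 571 and 875 beyond 2-fold. CCND1 (-0.49, adjusted p = 0.0346) was lost without R1 replicate 1, 3 or 4 or R2 replicate 1 or 2 (adjusted p up to 0.0984). MITF (0.40, adjusted p = 0.0787) did not pass, but did without R1 replicate 2 (adjusted p = 0.0284). RPS6 was lower (-0.55, adjusted p = 0.003), and RB1 (0.09, adjusted p = 0.597), CDKN2A (0.13, adjusted p = 0.442), MAP2K2 (0.05, adjusted p = 0.779) and PIK3CA (-0.08, adjusted p = 0.640) did not pass.

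The genes highest in R2 relative to R1 were HBE1 (63.5 ± 13.3 against 0.0948 ± 0.0879, log2 fold change 6.74, SE 0.21, adjusted p = 1.9e-11) and OR51B4, an olfactory receptor gene (36.2 ± 1.25 against 0.0326 ± 0.0222, 6.11, adjusted p = 1.2e-12), whose annotated spans on chromosome 11 overlap. SSX1, a cancer-testis antigen (5.32, adjusted p = 5.7e-10), SDPR (5.11, adjusted p = 7.7e-11) and CPVL, a carboxypeptidase (5.01, adjusted p = 4.9e-11), came next. G0S2 (0.106 ± 0.0805 against 63.5 ± 14.1, -6.71, adjusted p = 3.5e-12), TNFAIP8L2 (-5.93, adjusted p = 2.3e-12), SNHG14 (3 reads in R2, ratio of the higher to the lower group 1159, 95% counting interval 396 to 5621), VGF, a secreted neuropeptide precursor (-5.46, adjusted p = 1.8e-05), and FAM101B (no read in R2, at least 729-fold lower) were lowest. The named genes called here had non-overlapping ranges except CCND1, HMMR, PMVK and RPS6KB1. HBE1 lies on chromosome 11, 5268345 to 5505652 and OR51B4 on chromosome 11, 5301014 to 5301946, in a stretch in which 111 of 149 genes were higher in R2, found after the values were seen.

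Of mitochondrial genome transcripts 13 rose and 0 fell of 13 measured (13 and 0 adjusted over the list alone), median 1.70, with MT-ATP8 (2.00, adjusted p = 5.6e-05) and MT-ND4L (1.99, adjusted p = 0.00011). MT-ND6, chosen after its values were seen, was among them with overlapping ranges, and edgeR and DESeq2 each called 12. By camera the mitochondrial genome list had adjusted p = 8.6e-06, and adjusted p = 0.683 with an estimated correlation. Of ribosomal protein genes 2 rose and 60 fell of 77 measured (3 and 62 adjusted over the list alone), median -0.84, with RPS21 (-1.89, adjusted p = 1.6e-07) and RPL34 (-1.87, adjusted p = 2.0e-07). By camera the ribosomal protein list had adjusted p = 1.1e-15, and adjusted p = 0.683 with an estimated correlation. RPL27A (0.61, adjusted p = 0.0028) and RPL28 (0.48, adjusted p = 0.0136), chosen after their values were seen, were higher. Of the respiratory chain genes 6 rose and 24 fell of 51 measured (6 and 24 adjusted over the list alone), median -0.32, with NDUFB8 (-1.67, adjusted p = 1.1e-06) and COX6A1 (-1.60, adjusted p = 2.8e-06). By camera the respiratory chain list had adjusted p = 0.0016, and adjusted p = 0.869 with an estimated correlation. Of MHC class II genes 1 rose and 11 fell of 12 measured (1 and 11 adjusted over the list alone), median -1.67, with HLA-DRB1 (-2.66, adjusted p = 1.8e-06) and HLA-DRB5 (-2.55, adjusted p = 1.9e-05), and RFX5, chosen after its values were seen, higher (0.46, adjusted p = 0.0012). By camera the class II list had adjusted p = 2.9e-05, and adjusted p = 0.547 with an estimated correlation. Of MHC class I genes 1 rose and 11 fell of 19 measured (1 and 11 adjusted over the list alone), median -0.42, with the peptide transporter TAP1 (-1.34, adjusted p = 5.8e-06) and HLA-B (-1.38, adjusted p = 0.0052). By camera the class I list had adjusted p = 0.0154, and adjusted p = 0.731 with an estimated correlation. TAPBP, chosen after its values were seen, was higher (0.74, adjusted p = 0.00071), and the list was lost without R1 replicate 2 (adjusted p = 0.0714). R1 also had the lower mitochondrial share.

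Of E2F and DNA replication genes 17 rose and 0 fell of 51 measured (16 and 0 adjusted over the list alone), median 0.24, with E2F8 (2.14, adjusted p = 5.0e-05) and CHAF1B, a histone chaperone (1.14, adjusted p = 0.00065). By camera the E2F list had adjusted p = 0.0159, and adjusted p = 0.869 with an estimated correlation. Of G2/M and mitosis genes 10 rose and 1 fell of 40 measured (8 and 0 adjusted over the list alone), median 0.28, with HMMR (1.16, adjusted p = 0.0056). PRC1, chosen here after its values were seen, was lower (-0.48, adjusted p = 0.0422). By camera the G2/M list had adjusted p = 0.0455, and adjusted p = 0.869 with an estimated correlation. Both calls rested on R1 replicate 2, whose scores of both lists were the lowest of R1. Without it the adjusted p was 0.532 for E2F and 0.912 for G2/M, and G2/M was also lost without R2 replicate 3 (0.0818) or 4 (0.0786). Of p53 targets 3 rose and 10 fell of 26 measured (3 and 10 adjusted over the list alone), median -0.36, with CDKN1A, the CDK inhibitor p21, at 9.24 ± 5.52 against 61.0 ± 14.6 (-2.83, adjusted p = 2.8e-05) and PHLDA3 (-1.65, adjusted p = 1.9e-05). By camera the p53 list had adjusted p = 0.0474, and adjusted p = 0.506 with an estimated correlation. POLH (0.67, adjusted p = 0.00077), PLK2 (0.64, adjusted p = 0.0112) and BAX (0.30, adjusted p = 0.0241) were higher, chosen here after their values were seen, the latter pair with overlapping ranges. This call was lost without R1 replicate 2 (adjusted p = 0.0828), 3 (0.0519) or 4 (0.0661) or R2 replicate 1 (0.0587) or 2 (0.0501).

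Of the BCL2 family 1 rose and 6 fell of 17 measured (1 and 6 adjusted over the list alone), median -0.27, with no BIK read in R2 (at least 114-fold lower), BCL2A1 (-1.53, adjusted p = 0.00089) and BAX, as above, higher. By camera the BCL2 list had adjusted p = 0.0455, and adjusted p = 0.549 with an estimated correlation. The call was lost without R1 replicate 1 (adjusted p = 0.0538), 2 (0.0828) or 3 (0.0519) or R2 replicate 2 (0.0745). Of endothelial markers 0 rose and 6 fell of 6 measured (0 and 6 adjusted over the list alone), median -1.39, with VWF, von Willebrand factor (-1.78, adjusted p = 5.0e-05) and EGFL7 at 1 read in R2 (ratio of the higher to the lower group 1743, 95% counting interval 312 to 68862). By camera the endothelial list had adjusted p = 0.0002, and adjusted p = 0.506 with an estimated correlation. Of the leukocyte markers 0 rose and 3 fell of 3 measured (0 and 3 adjusted over the list alone), median -1.51, which were LAPTM5 (-2.87, adjusted p = 1.2e-05), CSF1R (-1.51, adjusted p = 0.0029) and CORO1A (-0.76, adjusted p = 0.00093, chosen here after its values were seen), lost without R1 replicate 2 (adjusted p = 0.0509) or R2 replicate 2 (0.0501). By camera the leukocyte list had adjusted p = 0.0435, and adjusted p = 0.535 with an estimated correlation. Summed leukocyte marker values were 23.7 ± 5.43 in R1, 10.03 ± 1.20 in R2 and 8.55 ± 1.17 in control. Reads of mouse host cells were not separated from these endothelial and leukocyte values. Leukocyte markers had 3 of 20 members in the files, and endothelial markers 6 of 15. Listed genes exceeded 1 CPM in at least 4 libraries, so a low marker could enter through R1 alone, which favours lower values in R2. Keratinocyte markers had 2 of 15 members in the files, too few for the list test, with 2 and 0 (up and down) in R1 against control, 0 and 1 in R2 against control and 0 and 2 in R2 against R1. None of the 7 red blood cell and 16 adipocyte and muscle markers were among the listed genes.

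**Figure D4:**
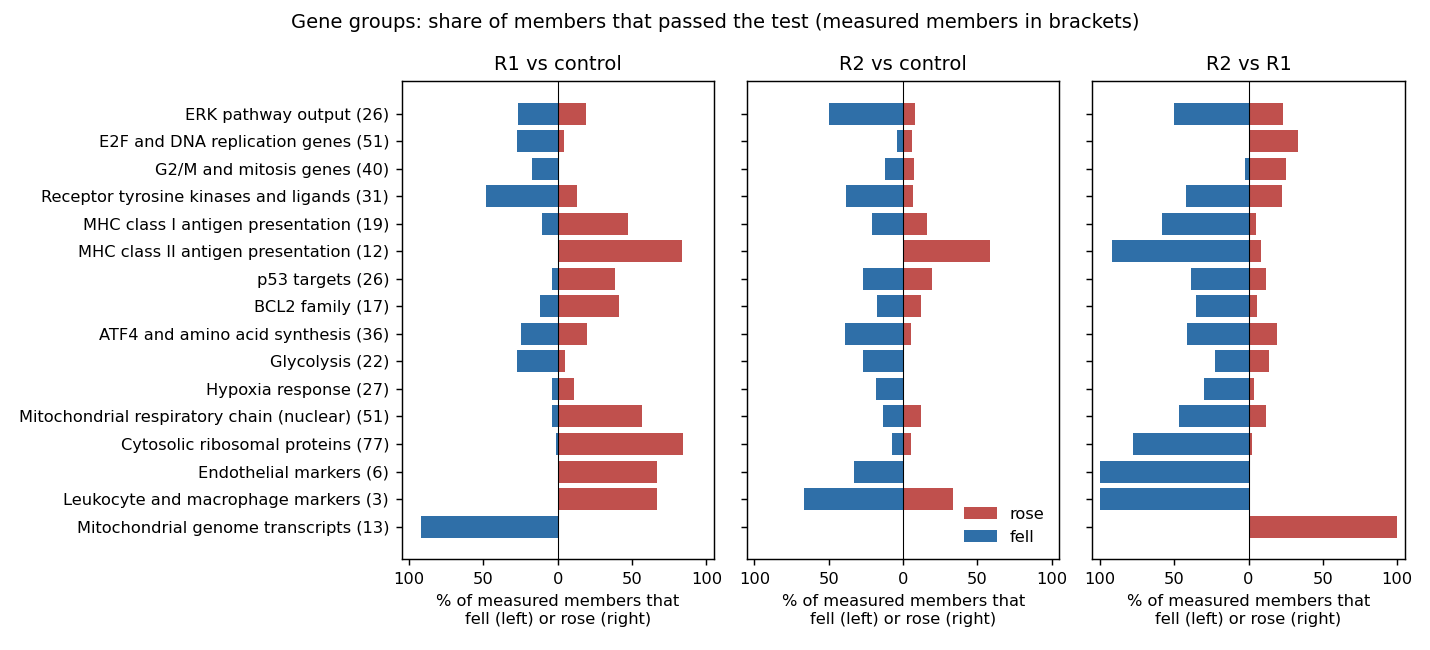
Percent of the measured members of 16 gene groups that fell (bars to the left) or rose (bars to the right) on the x axes, for R1 against control, R2 against control and R2 against R1, with the number of measured members in brackets. MHC class II genes rose in both comparisons with control (10 and 7 of 12), while ribosomal protein mRNAs rose in 65 of 77 members in R1 and in 4 in R2.

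Lists not called between R2 and R1 are given as higher and lower members. ERK pathway output had 6 and 13 of 26 (6 and 13 alone, adjusted p = 0.170), with TFAP2C (3.88, adjusted p = 2.4e-07) and PHLDA1 (-1.97, adjusted p = 3.4e-06). RAS-RAF-MEK-ERK components had 8 and 6 of 23 (8 and 6 alone, adjusted p = 0.879). Cyclin D-CDK4/6-RB components had 4 and 7 of 21 (4 and 7 alone, adjusted p = 0.711). PI3K-AKT-mTOR-S6 components had 12 and 5 of 35 (12 and 5 alone, adjusted p = 0.299). Receptor tyrosine kinases had 7 and 13 of 31 (8 and 13 alone, adjusted p = 0.652), with the EGFR ligand AREG (-2.90, adjusted p = 2.8e-06). Melanocyte differentiation had 2 and 7 of 15 (2 and 7 alone, adjusted p = 0.134), with PMEL (-1.58, adjusted p = 3.6e-05). The undifferentiated list had 10 and 8 of 31 (10 and 8 alone, adjusted p = 0.604). The neural crest-like list had 3 and 7 of 13 (3 and 7 alone, adjusted p = 0.432), with GFRA1 (4.39, adjusted p = 4.7e-09). YAP/TEAD targets had 10 and 4 of 23 (11 and 4 alone, adjusted p = 0.288). Extracellular matrix had 7 and 10 of 35 (7 and 10 alone, adjusted p = 0.429), with LAMA4 (-4.13, adjusted p = 5.8e-08) and VCAN (1.56, adjusted p = 7.7e-07). Interferon response had 6 and 12 of 42 (6 and 12 alone, adjusted p = 0.350). NF-kB had 1 and 8 of 26 (1 and 6 alone, adjusted p = 0.288), with TNFAIP2 (-4.34, adjusted p = 2.1e-09) and IL6 (2.70, adjusted p = 9.4e-05).

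ATF4 and amino acid synthesis had 7 and 15 of 36 (7 and 17 alone, adjusted p = 0.140). The unfolded protein response had 0 and 6 of 23 (0 and 4 alone, adjusted p = 0.178), called down without R1 replicate 1 (adjusted p = 0.0468). Cholesterol synthesis had 1 and 1 of 24 (1 and 0 alone, adjusted p = 0.696), with SC5D (1.62, adjusted p = 0.0002) and PMVK (-0.39, adjusted p = 0.0354), the latter lost without R1 replicate 1 or 3 or R2 replicate 1, 2 or 4 (adjusted p up to 0.101). Fatty acid synthesis had 6 and 2 of 19 (6 and 2 alone, adjusted p = 0.413). Glycolysis had 3 and 5 of 22 (3 and 5 alone, adjusted p = 0.432), with LDHA (1.09, adjusted p = 0.00058). Hypoxia response had 1 and 8 of 27 (0 and 7 alone, adjusted p = 0.124), with STC1 (-2.59, adjusted p = 4.7e-05). Lysosome had 6 and 8 of 34 (6 and 8 alone, adjusted p = 0.646), with CTSL (-1.58, adjusted p = 4.9e-06) and CTSD (1.16, adjusted p = 5.2e-05). NRF2 targets had 4 and 6 of 20 (4 and 6 alone, adjusted p = 0.636), with TXN (-1.06, adjusted p = 5.8e-05). Fibroblast markers had 2 and 4 of 8 (2 and 4 alone, adjusted p = 0.288), with CSPG4 (-2.80, adjusted p = 2.8e-05). Median and mean differed in sign for cyclin D-CDK4/6-RB (0.09, -0.15, test down) and RAS-RAF-MEK-ERK (0.05, -0.08, test up). No list call in any of the 3 comparisons held with an estimated correlation, where the lowest adjusted p was 0.534, 0.946 and 0.506, and raw p-values under 0.05 numbered 2, 1 and 2. The set test fry called 13, 8 and 15 lists.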

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

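The fit without R1 replicate 2 and R2 replicate 3 together was chosen after the data were seen, and the other tests of this part beforehand. In 162 sets of 4 values (a list score, a fixed gene, or a library measure such as depth, in a group), 20 held a library whose gap to its nearest neighbour took most of the range of its group. Chance sets a library apart in about 1 in 20 such sets. A list score is the mean log2(value + 0.5) of the members.

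R1 replicate 2 stood apart in most of them. Its residuals from the group mean correlated with those of control replicates 3 and 4 (0.43 and 0.41) and inversely with control replicates 1 and 2 (-0.52 and -0.31). Its scores were the lowest of R1 for E2F and DNA replication genes (5.09, the nearest other at 5.85) and for G2/M and mitosis genes (5.62, nearest 6.64). They were the highest of R1 for hypoxia response (6.13, nearest 4.94), NF-kB and inflammatory secretion (5.93, nearest 4.76), the unfolded protein response (7.23, nearest 6.25) and extracellular matrix (6.17, nearest 5.42). The same held for melanocyte differentiation (4.21, nearest 3.81), the neural crest-like state (4.89, nearest 4.55), type I interferon response (4.10, nearest 3.81) and ATF4 and amino acid synthesis (5.79, nearest 5.52). MAP2K1 was also highest in that library, at 122 against 94.6 in the nearest. Without it and R2 replicate 3, the adjusted p of the comparison of R2 with R1 was 0.627 for the E2F list and 0.946 for the G2/M list, and the direction of the latter turned down.

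Other libraries stood apart in 1 or a few measures. R2 replicate 2 had a low E2F score (5.80, nearest 6.05) and a high hypoxia score (4.77, nearest 4.50). R2 replicate 1 was low in cholesterol synthesis (5.57, nearest 6.18) and fatty acid synthesis (6.41, nearest 6.73). R1 replicate 1 was low in fatty acid synthesis (6.28, nearest 6.70). R2 replicate 3 was low in mitochondrial genome transcripts (10.7, nearest 11.7), and R2 replicate 4 in MAP2K2, with a value of 202 (nearest 246). Control replicate 3 was low in cyclin D-CDK4/6-RB components (5.78, nearest 5.85) and high in the leukocyte markers (1.72, nearest 1.30).

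CDK4, MAP2K1 and DUSP6 moved in opposite directions in R1 and R2 against control, and the direct test found each of them lower in R2 than in R1. The log2 fold change of R2 against R1 was -1.13 for CDK4 (adjusted p = 1.1e-05), -1.44 for MAP2K1 (adjusted p = 2.8e-07) and -1.28 for DUSP6 (adjusted p = 4.0e-05). All 4 R2 libraries were below all 4 R1 libraries for each.

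For the numbers of genes called, the real grouping of the libraries was set beside other splits. Mixed splits carry the group difference as spread within groups, which lowers their calls. Replicates may be repeated libraries, so the splits cannot exclude chance differences between single tumours or cultures. For R1 against control 1 of the 35 splits of the 8 libraries, the real one, gave as many genes (5667, highest other 0), and likewise for R2 against control (1 of 35, 3667, highest other 0) and R2 against R1 (1 of 35, 6053, highest other 8). At an unadjusted p under 0.05 in limma, the only tool used on the splits, the real splits gave 6640, 5140 and 6920 genes and the highest others 2692, 1816 and 2305. For genes called in both groups in 1 direction 1 of 100 drawn splits, the real one, gave as many (1613, highest other 0). The splits for the mean of R1 and R2 against control used 1 mean for each part, unlike the fit that called 4553 genes. There 2 of 100 drawn splits gave as many. The real value was 1998 and the highest other 2569, from the split that set R2 against the rest, which points to a structure of the samples. Chance cannot be excluded for the numbers of lists called by camera. For R1 against control 35 of 35 splits called as many (real 5, highest other 20), for R2 against control 25 of 35 (7, highest other 16) and for R2 against R1 21 of 35 (11, highest other 20).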

How the results depend on the processing

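The alternatives chosen after the data were seen were edgeR on recovered reads, added values of 0.1 and 1, a mean of at least 5, scaling without mitochondrial transcripts and the fit without R1 replicate 2 and R2 replicate 3. No called named gene reversed its direction in any alternative run here, while the balance of risen and fallen genes did in some of them, as for R1 against control with DESeq2 size factors (2784 and 2907, from 2900 and 2767). The G2/M list turned down between R2 and R1, without a call, in the fit without both libraries (adjusted p = 0.946). Counts of genes stayed within 1.5 times of those reported under the other scalings, edgeR, DESeq2, both added values, both filters, the fits of only the groups compared and the replicate block. They ranged from 4541 to 5869 for R1 against control, 2782 to 4408 for R2 against control, 4888 to 6206 for R2 against R1, 3516 to 4825 for the mean and 1185 to 1733 in both groups. The lowest came from the filter on a mean of at least 5, which removed 2532 genes. The filter on a deposited, scaled value of at least 1 in at least 4 libraries removed 22. The other scalings moved the median log2 fold change of all genes by -0.0189 to 0.0420.

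Stricter thresholds lowered the counts by construction. At an adjusted p under 0.01 there were 2135 genes for R2 against control, 2785 for the mean and 862 in both. Against a fold of 1.5 (limma treat) there were 1006, 579 and 1067 for the 3 pairwise comparisons, 571 for the mean and 214 in both. With an estimated correlation, camera called 0, 0 and 0 lists, where unadjusted p-values under 0.05 numbered 2, 1 and 2. This ended all 23 list calls. The set test fry, which asks another question, called 13 lists for R1 against control, 8 for R2 against control and 15 for R2 against R1. Without R1 replicate 2 and R2 replicate 3, lists called for R2 against R1 numbered 6, with E2F, G2/M, p53, BCL2 and MHC class I lost, and the cause was not tested. Across genes r fell to 0.29 where control replicates 1 and 2 served R1 and 3 and 4 served R2, and the cause was not tested. Its other control splits gave 0.38 to 0.43.

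With each library left out in turn, counts ranged from 4943 to 5877 (R1 against control), 2795 to 4223 (R2 against control), 5245 to 6171 (R2 against R1), 3567 to 5069 (mean) and 1220 to 1800 (both), and r from 0.40 to 0.44. Lists called ranged from 5 to 7, 4 to 7 and 5 to 11. The 4 came without control replicate 3 or 4 and the 5 for R2 against R1 without R1 replicate 2, and the cause was not tested.

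With the replicate number as a block, 5798, 3733 and 6162 genes and 5, 7 and 9 lists were called. The BCL2 and p53 lists were lost there for R2 against R1 (adjusted p = 0.0520 for both). Residual correlations of libraries with the same number ran from -0.31 to 0.39, with 5 of 12 pairs over 0.1, and 3 libraries correlated best with their own number, so the numbers were not taken to pair samples.

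A few named genes near the threshold changed sides. RPS6KB1 in R1 was called with DESeq2 and with its size factors, and PIK3CA in R1 with upper quartile scaling, edgeR, DESeq2 and the block. RB1 in R1 was lost with upper quartile scaling and without both libraries, CCND1 in R2 with the block, and DNAJC3 between R2 and R1 without both libraries. CDKN2A in R2 was called with DESeq2, and MITF between R2 and R1 without both libraries. The cause was not tested. A fit with no filter at all was not run, since the deposited genes were already filtered, and limma treat took the place of edgeR glmTreat. DESeq2 gave no adjusted p for 4 genes in each comparison. Depth limits genes with few reads, where ratios are given with counting intervals or as bounds.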

Other observations

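The search for stretches of neighbouring genes was chosen after the values were seen. Genes that changed together lay in long stretches of single chromosomes, in windows of 25 neighbouring genes whose median passed what 1000 permutations of gene order gave. The limit of the absolute median was 0.582 for R1 against control, 0.488 for R2 against control and 0.626 for R2 against R1. Overlapping windows were joined, so the median of a whole stretch can fall short of the limit. In R2 against control, 289 of 371 genes fell and 10 rose along chromosome 15, from 20379495 to 101976543, with a median log2 fold change of -0.76. This stretch holds MAP2K1, LOXL1 and SNHG14, and also B2M, the light chain of MHC class I (-0.59, adjusted p = 0.0023). A stretch of chromosome 1 from 114582848 to 121185539, which holds NRAS, was higher (25 genes, median 0.57), as was one of chromosome 19 (30 genes, median 0.44). Others on chromosome 12 were lower, from 990509 to 10223130 (71 genes, median -0.51), which holds ENO2 and SLC2A3, and from 51186936 to 53626410 (32 genes, median -0.46).

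In R1 against control, lower stretches lay on chromosome 11 from 167784 to 32105755 (98 of 146 genes fell, median -0.65), which holds HBE1, IRF7, ADM and LDHA, and on chromosome 12 from 6666477 to 42459715 (74 of 120 fell, median -0.59), which holds ENO2 and SLC2A3 too. Chromosome 4 from 53285 to 37686376 had 70 of 98 fallen (median -0.71). Shorter lower stretches lay on chromosomes 7 (45 genes, median -0.49), 15 (25 genes, median -0.62) and 18 (29 genes, median -0.56). A stretch of chromosome 6 from 31959080 to 33314387, with the MHC class II genes, held windows that were higher. Its 39 genes together had a median of 0.24, short of the limit, with 16 risen and 5 fallen. The stretches covered 6.11% of placed autosomal genes in R1 against control, 6.47% in R2 against control and 7.40% in R2 against R1.

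Genes of chromosome 17 from 508668 to 21090615 were lower in both groups, with a median of -0.76 in R1 (137 of 193 fell, 10 rose) and -0.88 in R2 (170 fell, 4 rose). They include MYH10 and SOX15. GC content, transcript length and level were argued against, since matched genes of other autosomes had a median of -0.0199 in R2 and 0.0352 in R1, and so were a few libraries, since every R1 and R2 library lay below every control library by at least 0.556 in its segment median. Loss of a copy of the segment stays open, as do a gain in the shared controls and a selected clone that already differed. Each of these could lower the segment as a whole, so its median cannot tell them apart. The segment was picked out for its lower values, and no DNA data were analysed here. MYH10 and SOX15, nearly without reads in both groups, fell far more than the segment medians. A shift of the segment as a whole therefore does not account for the size of their falls, whose cause was not tested. Of the 770 placed genes lower in both groups, 131 lie in this segment.

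For the higher NRAS in R1 (log2 fold change 2.95), the tables argue against a regional gain, since the 14 tested genes within 1 Mb had a median of 0.157, above 73.1% of windows of as many genes. They argue against scaling, with a lowest value of 2.93 under the other scalings. A gain of NRAS alone, higher transcription and a more stable mRNA stay open and were not tested, nor were reads of mouse host cells. In R2 the same 14 genes had a median of 0.40, above 99.1% of windows, with 9 risen and 0 fallen, while NRAS itself did not pass (0.19, adjusted p = 0.304). A biological difference of R1 stays among the open explanations.

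For the higher ribosomal protein mRNAs in R1 (median 0.81), matched genes argue against transcript length and level. Lists of other genes matched on both had a median of -0.124 (highest of 10000 lists 0.196), and -0.101 with GC content matched too (highest 0.159). Scaling without mitochondrial transcripts left the median at 0.802, and it stayed at 0.691 or above with any 1 library left out, lowest without R1 replicate 3. A biological difference between the groups stays open, as a hypothesis, and so do RNA quality and library batches, for which the labels give no values. The lower share of mitochondrial transcripts in R1 went along with it.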
